A study of Mus musculus with 258 samples.

How the data were processed

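Hi-C measures how often pairs of genomic positions are ligated together after crosslinking, and a loop is a pair of anchors whose contact count stands above its surroundings. Per the labels, B cells were isolated from the spleens of mice 6 to 8 weeks old, and were either resting (0 h) or activated for 72 h with lipopolysaccharide (50 µg/mL), interleukin 4 (2.5 ng/mL) and an antibody against CD180 (0.5 µg/mL). The labels assign 8 Hi-C libraries to resting cells and 26 to cells activated for 72 h. A further 59 Hi-C libraries, from other treatments and from embryonic stem cells, and 165 libraries of other assays were not analysed here. The values used were 2 deposited loop lists, 1 for resting and 1 for activated cells. The name of the activated list gives no time. It was taken as the 72 h state because, per the deposited description of the maps, this was the one activated state without gene deletion or inhibitor.

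Per the submitters' processing notes, the tools named were BWA and Juicer and the genome build was mm9. Their versions, and the loop caller with its settings, are not given in the sources used here. Per the file headers, each loop carries an observed contact count at its pixel. The deposited contact counts were whole numbers and were not normalized. Per the file headers, each loop also carries expected contact counts from 4 local backgrounds (donut, lower left, horizontal and vertical), a false discovery rate (a q-value) for each of them, and the number of enriched pixels merged into the loop. The pixels were 5 kb wide. In the values themselves the highest deposited q-value was 0.0939 to 0.0942 against the horizontal and vertical backgrounds in the resting list and 0.0988 to 0.0998 in the activated list. The lowest ratio of observed to donut-expected counts was 1.75 in the resting list and 1.76 in the activated list, and the shortest loop was 35 kb in both. The lists thus hold loops that passed the authors' limits, and a loop missing from a list is a loop not called, not a loop shown to be absent.

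Each state has 1 pooled list, so every value is the authors' value for a state, with no replicates, and no p-values between states were computed. Intervals are 95% intervals that cover counting error (Wilson for shares, exact conditional binomial for ratios of counts) or the choice of loci (10000 bootstraps over whole chromosomes). They do not cover variation between animals or libraries. Library totals were not given in the sources used here. The relative depth of the maps was therefore estimated as the median ratio, activated over resting, of donut-expected counts at shared loops, which was 1.55 (bootstrap interval 1.51 to 1.58). Observed counts ranged from 19 to 999 in the resting list (median 61) and from 14 to 932 in the activated list (median 67).

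A loop was called shared when both its anchors, widened by 10 kb on either side, overlapped both anchors of a loop in the other list by at least 1 bp, which allows a distance of up to 20 kb at each end. Chance sharing was taken from 1000 circular shifts of 1 list along each chromosome. Length was the distance between anchor midpoints. Strength was the observed count over the donut-expected count, and for shared loops the log2 ratio of strengths was computed over one-to-one pairs. For loops per anchor, anchors of both lists within 10 kb were merged. To lower the depth of the activated list, its observed counts were thinned by the single depth ratio of 1.55 with seeded binomial draws, the expected counts were divided by it, and loops were kept when they still passed the lowest ratios and the highest Poisson p-values seen in the resting list. On data simulated from the resting list, matching recovered 61.6% shared loops where 60.3% had been put in (1866 loops). True partners were moved by at most 10 kb at each end, within the tolerance, so they were matched by design. The median log2 strength ratio came out at 0.01 where 0 was put in. Simulated partners did not have to pass the limits of the lists, so bias from that selection was not tested. After simulated deepening and thinning back, 87.1% of the 1866 resting loops were kept.

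The rules for named loops, the matching rule and most of the other settings tried were fixed before the data were examined. Loops were named when they were among the 5 with the highest strength in their class (resting-only, activated-only or shared) with an observed count of at least 30, among the 5 largest rises or 5 largest falls of strength among shared loops, or the longest of a list. That rule did not say how to combine the states for shared loops, so these were ranked by the geometric mean of the strengths in both states, with at least 30 contacts in each. Chromosome Y filled most of these places, so the strongest loops without chromosome Y were named as well, a choice made after the values were seen. Alternatives covered the q-value limit, the strength limit, merged pixels, widening of anchors, backgrounds, depth, summary of length and each chromosome left out. Without chromosome Y, loops of 100 kb or longer, a common Poisson p limit, a thinning factor for each length class (loops over 1000 kb taking that of 500 to 1000 kb) and a match of strict resting loops to the full activated list were alternatives added after the data had been seen. Coordinates are 1-based positions in mm9. The gene table at hand is for GRCm38 and was not used to name genes, because loops on chromosome 7 reach 152425000 while the last gene of that table ends at 145324059. Gene lists at anchors and the orientation of CTCF motifs were not analysed here. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.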

Results

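Chromatin loops were compared between resting mouse splenic B cells and B cells activated for 72 h, from 1 pooled Hi-C loop list per state. The labels assign 8 libraries to the resting group and 26 to the activated group, and whether each pooled map used every one of them is not given in the sources used here. There are no replicate lists, so the intervals below cover counting error or the sampling of chromosomes and do not measure differences between animals. The activated map was estimated to be deeper, from 1.55 times the expected contacts at loops found in both states. Without chromosome Y this ratio ran from 1.65 up to 50 kb to 1.23 over 500 to 1000 kb. A single depth factor is therefore approximate. The comparison addresses how the folding of the genome differs between quiescent and activated B cells.

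Activated B cells had more called loops than resting B cells. The authors' lists held 1866 loops in resting cells and 4315 in activated cells, a ratio of 2.31 (exact 95% interval 2.19 to 2.44). The activated count was higher on each of the 21 chromosomes. Among the 19 autosomes the ratio ran from 1.964 on chromosome 17 to 2.81 on chromosome 18. Chromosome 11 had the highest autosomal density in both states, with 164 loops in resting cells and 387 in activated cells, or 1.35 and 3.18 loops per Mb from the start of the chromosome to its last loop. Chromosome X had the lowest, with 15 and 58 loops (0.0916 and 0.354 per Mb), and its ratio of 3.87 had a wide interval (2.16 to 7.35). On chromosome Y the counts were 37 and 48, a ratio of 1.30 whose interval included 1 (0.827 to 2.05). When the activated list was thinned by the single factor of 1.55, 3564 loops were left and the ratio was 1.91 (1.81 to 2.02). With a common Poisson p limit of 1e-05 for both lists, a choice made after the data were seen, the thinned ratio was 1.50 (1.41 to 1.60).

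Most resting loops were also called in activated cells, and most activated loops were not called in resting cells. Of the resting loops, 1216 were shared (65.2%, Wilson interval 63.0 to 67.3), and 650 were called in resting cells alone. Of the activated loops, 1219 were shared (28.3%, 26.9 to 29.6), and 3096 were called in activated cells alone. With 4315 activated and 1866 resting loops, one-to-one matching could not have made most activated loops shared. That most activated loops were activated-only thus follows from the sizes of the lists. Circular shifts gave chance shares of 1.31% and 0.559% on average, with highest values of 4.98% and 1.88% over 1000 shifts. The share of resting loops found in activated cells ran from 56.2% on chromosome 13 to 73.2% on chromosome 15 among autosomes, and was 94.6% on chromosome Y (35 of 37). The 2 lists gave 1212 one-to-one pairs, of which 449 (37.0%) lay at the same pixel and 994 (82.0%) within 10 kb summed over both anchors. The share depended on the tolerance: with anchors not widened it was 24.1% of resting and 10.4% of activated loops.

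Loops of activated cells were longer. The median distance between anchors was 90 kb in resting cells (bootstrap interval 85 to 102.5) and 140 kb in activated cells (135 to 155), a difference of 50 kb (45 to 55). Shared loops had a median of 115 kb in both lists, resting-only loops 55 kb (50 to 60) and activated-only loops 155 kb (150 to 165). Loops of up to 50 kb made up 49.7% of resting-only loops (323 loops) and 10.8% of activated-only loops (333 loops). Short loops were about equally numerous in the lists, and the excess of activated loops widened with length up to 1000 kb.

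Up to 50 kb, 554 loops were called in resting and 557 in activated cells, a ratio of 1.01 (0.892 to 1.13). The ratio was 2.04 over 50 to 100 kb, 2.80 over 100 to 200 kb, 3.85 over 200 to 500 kb and 6.33 (4.50 to 9.12) over 500 to 1000 kb, where 39 resting and 247 activated loops were called. Above 1000 kb it was 2.35 (26 and 61 loops), and without chromosome Y, a choice made after the data were seen, it was 3.13 (1.75 to 5.88, 16 and 50 loops). After thinning by 1.55 at every length, the ratio was 0.789 (0.694 to 0.896) up to 50 kb and 5.46 over 500 to 1000 kb. The expected counts differed by 1.65 times up to 50 kb and by 1.23 times (1.02 to 1.46) over 500 to 1000 kb, and with a factor for each length class, chosen after the data were seen, these ratios were 0.778 (0.684 to 0.884) and 6.08 (4.32 to 8.76). Thinning also loses loops by chance: of 1866 resting loops of all lengths, simulated deepening and thinning back kept 87.1%, so a thinned ratio below 1 up to 50 kb does not by itself show fewer short loops in activated cells. The share of resting loops that were shared was 41.7% up to 50 kb, 65.9% over 50 to 100 kb, 78.8% over 100 to 200 kb, 84.4% over 200 to 500 kb, 76.9% over 500 to 1000 kb and 61.5% above. The share of activated loops that were shared fell with length up to 1000 kb, at 40.2%, 33.7%, 27.8%, 21.8% and 12.6%, and was 26.2% above. The number of resting loops limits this share: 554 stood against 557 activated loops up to 50 kb, and 39 against 247 over 500 to 1000 kb. Its fall therefore does not by itself show poorer matching of long loops. The median length of resting-only loops was 0.478 of that of shared resting loops (0.40 to 0.524), and 0.773 of it when anchors were not widened.

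**Figure D1:**
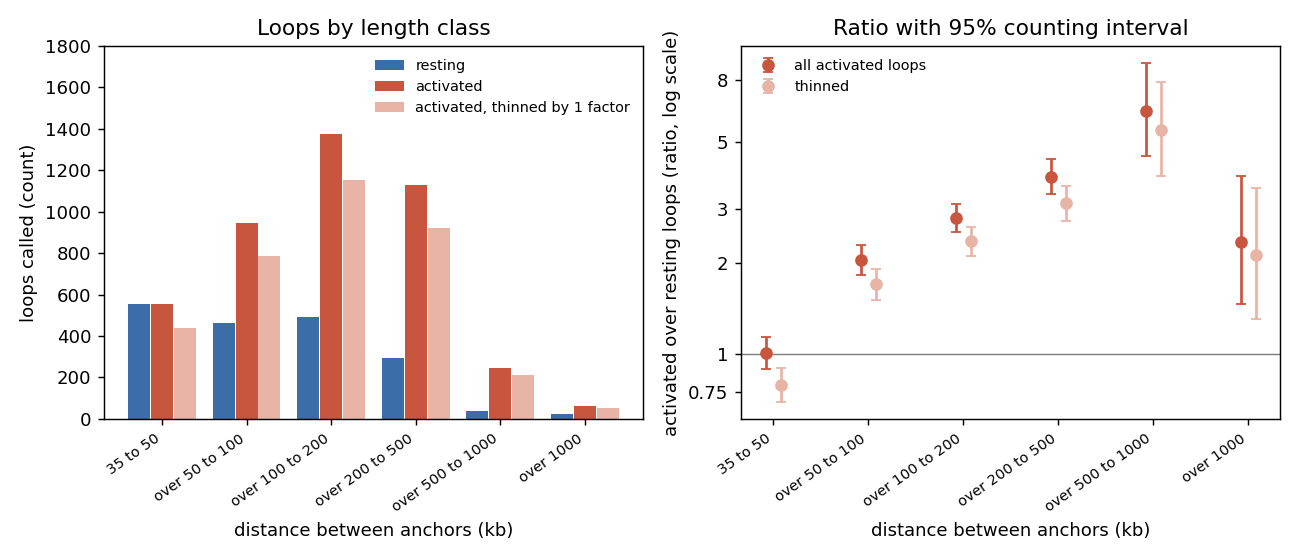
Loops called per class of anchor distance in kb (left, counts, in resting cells, activated cells and the activated list thinned by the single factor of 1.55) and the ratio of activated to resting loops with 95% counting intervals (right, log scale). The ratio is 1.01 up to 50 kb and 6.33 over 500 to 1000 kb.

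**Figure D2:**
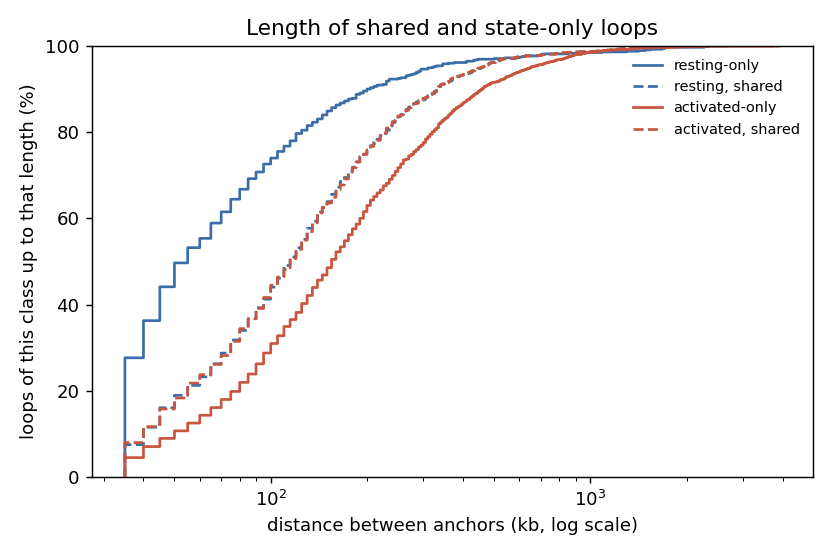
Cumulative percentage of loops (vertical) by distance between anchors in kb (horizontal, log scale) for resting-only, activated-only and shared loops, the last drawn from each list. Medians are 55 kb for resting-only, 115 kb for shared and 155 kb for activated-only loops.

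Loops called in both states differed little in median strength, with a shift that was not uniform over lengths. The median observed over expected count of paired shared loops was 2.84 in resting and 2.93 in activated cells, and the median log2 ratio was 0.05 (bootstrap interval 0.03 to 0.07). The ratio was higher in activated cells for 687 of 1212 pairs (56.7%, 53.9 to 59.4). State-only loops differed from each other: the median was 2.27 for resting-only and 2.80 for activated-only loops. These classes also differed in median length (55 and 155 kb) and in median expected count (28.6 and 20.9). No comparison at matched length was made. Without chromosome Y, the median log2 ratio of shared loops was 0.01 (-0.02 to 0.04) up to 50 kb, 0.02 (-0.01 to 0.07) over 50 to 100 kb, 0.10 (0.06 to 0.12) over 100 to 200 kb, 0.06 (0.01 to 0.10) over 200 to 500 kb and 0.23 (0.09 to 0.34, 25 pairs) over 500 to 1000 kb. A change of over 2-fold was seen in 8 shared loops, 5 higher and 3 lower in activated cells. The small median shift depended on the background, at 0.022 with the horizontal, 0.020 with the vertical and -0.029 with the lower left one. The SD of the log2 ratio over pairs was 0.32, against a median counting error of 0.24, and 154 pairs (12.7%) lay outside 1.96 counting errors.

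Among shared loops outside chromosome Y, the loop on chromosome 3 from 105925001 to 106115000 (mm9) had the largest rise in ratio, from 3.06 to 7.48 times the expected count (log2 ratio 1.29, counting SE 0.19, expected counts taken as fixed). Its raw observed counts were 113 in resting and 111 in activated cells, and its expected count was 36.9 and 14.8. The observed count stayed nearly level although the activated map was estimated to be deeper, so in raw counts the change came from the expected count. The loop on chromosome 13 from 41380001 to 41670000 had ratios of 2.37 and 4.83 (log2 ratio 1.03, SE 0.22), from 60 and 139 observed contacts, and its activated partner began 1 pixel away, at 41375001. The loop on chromosome 8 from 123220001 to 123315000 had ratios of 1.94 and 4.55 (log2 ratio 1.23, SE 0.20), from 78 and 156 contacts, and its activated partner lay from 123205001 to 123325000. The largest falls in ratio outside chromosome Y were on chromosome 13 from 23525001 to 23615000, from 3.98 to 2.20 (log2 ratio -0.85, SE 0.17), and on chromosome 16 from 45195001 to 45415000, from 4.45 to 2.51 (log2 ratio -0.83, SE 0.27). Raw observed counts were not corrected for the activated map's greater depth, estimated at 1.55 times. At these loops they were 112 and 182 on chromosome 13 and 53 and 60 on chromosome 16. Their activated partners were shorter, from 23540001 to 23600000 and from 45215001 to 45410000, so these ratios compare different pixels. The remaining 2 of the 5 largest rises and 3 of the 5 largest falls were on chromosome Y, with log2 ratios of 1.42 and 1.35 and of -1.83, -1.36 and -1.07. By the geometric mean of the ratios in both states, the strongest shared loop outside chromosome Y spanned chromosome 1 from 85270001 to 87490000 and stood at 28.4 and 27.9 times its expected count in resting and activated cells. It rested on 437 and 691 observed contacts. On chromosome X the loop from 120115001 to 121310000 stood at 18.1 and 33.3 times, from 34 and 61 observed contacts over expected counts of only 1.87 and 1.83. Whether reads placed among repeated sequence account for these loops on chromosomes 1 and X was not tested.

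**Figure D3:**
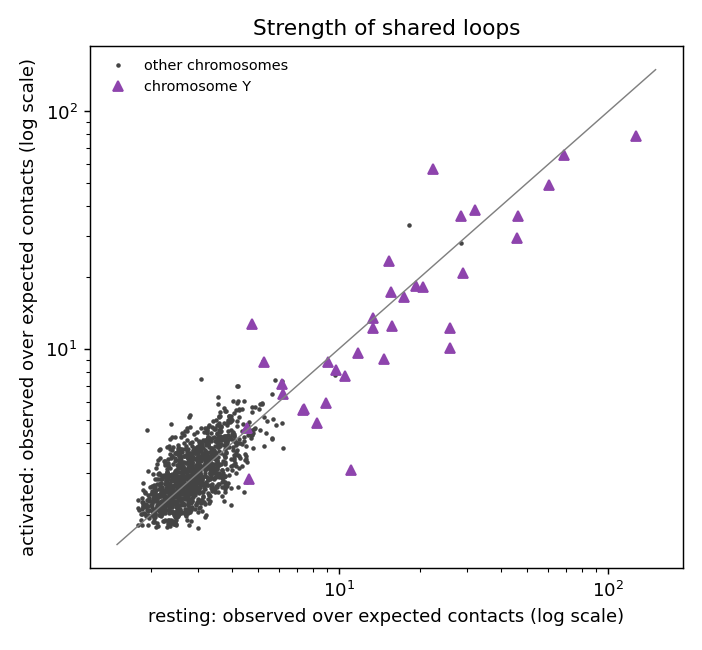
Observed over donut-expected contacts of shared loops in resting cells (horizontal) and activated cells (vertical), both on log scales, 1 point per pair, with triangles for chromosome Y and a line of equal values. Most points lie near the line, with a median log2 ratio of 0.05, and chromosome Y holds most of the pairs with high values.

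Most activated-only loops had no anchor in the resting list, and most resting-only loops had at least 1 anchor in the activated list. At least 1 anchor was in the other list for 33.8% of activated-only loops against 10.4% by chance (3.25 times), and for 66.3% of resting-only loops against 20.4% by chance (3.26 times). Relative to chance the classes thus stood alike, and the contrast between their shares went with the chance values. The difference between the classes was not tested. Of the activated-only loops, 66.2% had no anchor in the resting list, 27.7% had 1 and 6.07% had 2, against chance values of 89.6%, 9.15% and 1.25%. Of the resting-only loops, 33.7% had no anchor in the activated list, 51.4% had 1 and 14.9% had 2, against chance values of 79.6%, 16.4% and 3.97%. Merged anchors numbered 3113 in resting and 6521 in activated cells, and 2312 were in use in both, which is 74.3% of the resting and 35.5% of the activated anchors. Anchors with at least 2 loops made up 15.5% (14.2 to 16.8) in resting and 24.8% (23.7 to 25.8) in activated cells. Anchors with at least 3 made up 2.60% and 5.44%. After thinning, which left 3564 activated loops against 1866 resting loops, 21.9% of activated anchors had at least 2 loops. A longer list can by itself give more loops per anchor, and no comparison at equal list size was made.

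A region of 2.58 Mb on chromosome 13, from 21260001 to 23840000, went against the genome-wide direction. It held 19 resting loops and 8 activated loops, of which 5 in each list were shared. Of the 19 resting-only loops longer than 500 kb in the genome, 10 were on chromosome 13 and 9 of these lay in this region, while no other chromosome had more than 2. These 9 loops were 540 to 2350 kb long, with 23 to 55 observed contacts at 3.55 to 6.21 times the expected count. The longest activated loop within the region was 330 kb, although activated cells had 308 loops over 500 kb in the genome against 65 in resting cells. The longest resting loop in the genome was in this region, from 21260001 to 23615000, with 55 contacts at 5.23 times the expected count. At the 5 loops of the region in both lists the expected count in activated cells was 0.524 to 2.94 times that in resting cells (median 1.43), in part between different pixels. The region was singled out after the values were seen, and its loops share a few anchors and are not independent of each other.

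**Figure D4:**
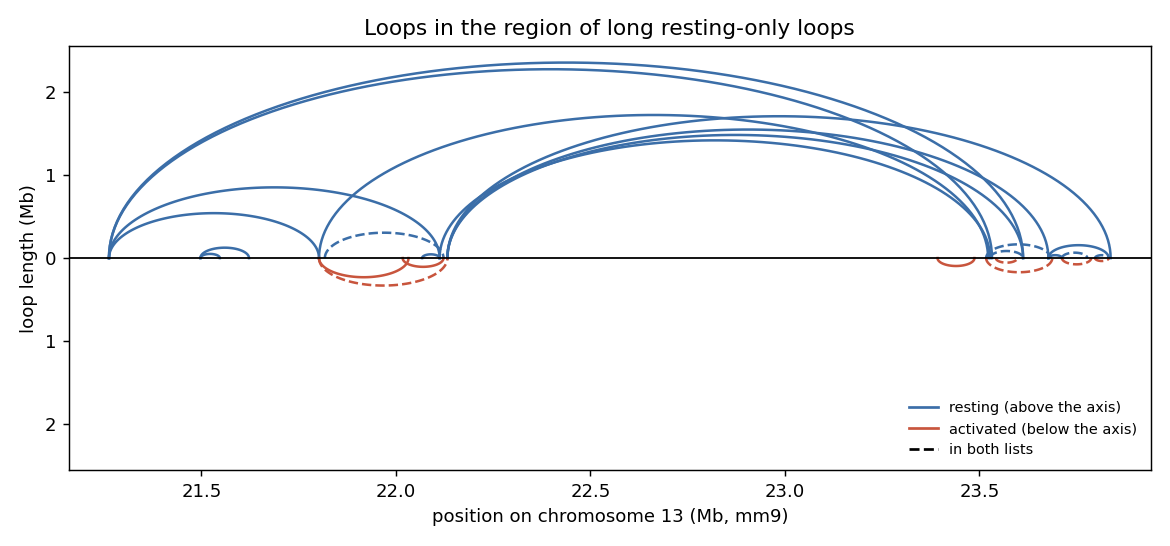
Loops within the region from 21260001 to 23840000 on chromosome 13 (horizontal, position in Mb, mm9) in resting cells (arcs above the axis) and activated cells (arcs below), with arc height equal to loop length in Mb and dashed arcs for loops in both lists. In this region 9 resting-only loops span 540 to 2350 kb, and the longest activated loop inside it spans 330 kb.

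Other strong loops called in 1 state lay on chromosomes 4 and 8, with a separate group on chromosome Y. The activated-only loop on chromosome 4 from 145145001 to 146895000 stood at 64.1 times its expected count with 129 contacts, and a second one nearby, from 144995001 to 145175000, at 15.1 times. The expected counts of these chromosome 4 loops were only 2.01 and 2.52, so their ratios rest on small denominators. The 129 contacts of the first were also above the activated list's median of 67. Whether reads placed among repeated sequence account for these chromosome 4 loops was not tested. On chromosome 8 a resting-only loop from 73655001 to 74360000 (4.51 times expected) and an activated-only loop from 73655001 to 74385000 (10.99 times) shared their left anchor. Their right anchors lay 25 kb apart, just beyond the tolerance of 20 kb, so the call of these loops as state-only depends on it. Further activated-only loops among the strongest outside chromosome Y were on chromosome 2 from 84960001 to 85405000 (9.24 times expected) and chromosome 5 from 130745001 to 131335000 (8.83 times). The resting-only loop on chromosome 3 from 67305001 to 67375000 stood at 4.40 times. The longest activated loop, on chromosome 13 from 85775001 to 89690000, was 3910 kb long and rested on 14 contacts.

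Chromosome Y loops all lay between 1260001 and 2880000 and had far higher ratios than loops elsewhere. Whether reads placed among repeated sequence account for these values was not tested, because no genome sequence was used here. Their median observed over expected count was 14.7 in resting and 15.02 in activated cells, against 2.61 and 2.83 on the other chromosomes. Of the loops above 10 times expected, 24 of 26 in resting and 30 of 36 in activated cells were on chromosome Y. The strongest shared one, from 1265001 to 2480000, stood at 126.8 times in resting and 79.1 times in activated cells, over expected counts of 2.59 and 4.61. The strongest activated-only one, from 1710001 to 2475000, stood at 129.6 times an expected count of 1.94. The strongest resting-only one, from 1790001 to 2880000, stood at 14.96 times with 756 contacts.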

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

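Without chromosome Y, loops of 100 kb or longer, a common Poisson limit, thinning factors by length class and strict resting loops against the full activated list were chosen after the data were seen. Of 95 alternatives, 56 stayed within the interval of the main value, 38 left it and 1 changed sign, and the cause was not tested unless given here. Of the 56, 21 left 1 chromosome each out of the same ratio, and others used the midpoint rule, which is the main rule by construction. For the number of chromosomes with more activated loops, a range of 14 to 31.5 stood in for an interval. The ratio of loops (2.31) was 2.62 with all q-values at most 0.01 and 3.27 for loops of 100 kb or longer. It was 1.91 with the activated list thinned and 1.94 with a thinning factor for each length class. With the single-factor thinning and a common Poisson limit together it was 1.50. It ran from 2.30 to 2.34 with each chromosome left out. Up to 50 kb the ratio (1.01) was 0.789 after thinning and 0.778 with a factor for each length class. These values crossed 1 but were not counted as changes of sign, because the main interval included 1. The shares of resting and of activated loops that were shared (65.2% and 28.3%) were 24.1% and 10.4% with anchors not widened, 74.1% and 32.4% with 25 kb, which follows from the tolerance, 62.3% and 23.7% with strict q-values, 60.2% and 31.5% after thinning, and 77.4% and 23.7% for loops of 100 kb or longer. Strict resting loops matched the full activated list in 69.2%. The length ratio of resting-only to shared loops (0.478) was 0.773 with anchors not widened. The log2 strength ratio (0.05) was 0.022 with the horizontal and 0.020 with the vertical background and changed sign to -0.029 with the lower left one. State-only loops with an anchor in the other list made up 33.8% in activated and 66.3% in resting cells; this was 26.5% and 57.4% with anchors not widened, 26.6% and 57.0% with strict q-values, 39.9% (activated) with 25 kb and 59.2% (resting) after thinning. Anchors with at least 2 loops (24.8% activated, 15.5% resting) were 17.9% and 10.98% with no gap, 30.4% and 18.8% with 25 kb, and 21.9% (activated) after thinning. Matching by midpoints within 20 kb is the main rule by construction; CTCF motif orientation, gene lists at anchors and separate pixel sizes were not run, because motifs and mm9 genes were not used here and every loop had 5 kb pixels. No paired analysis was possible because each state has 1 pooled list.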

Other observations

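The tests chosen only after the result was seen were that on the chromosome 13 region, the match of short activated loops, the thinned ratios with a common Poisson limit and with a factor for each length class, and the count of anchors with 6 or more loops. In windows of 5 Mb, 437 of the 469 windows with state-only loops had more activated-only loops, and 14 had more resting-only loops. Since the lists held 3096 activated-only and 650 resting-only loops, most windows would favour activated-only loops from these totals alone. The largest numbers of activated-only loops were on chromosome 10 from 75000001 to 80000000 (25, against 3 resting-only) and on chromosome 11 from 75000001 to 80000000 (24, against 5). The window with most resting-only loops was on chromosome 13 from 20000001 to 25000000, with 16 resting-only and 10 activated-only loops. On chromosome 9, the window from 115000001 to 120000000 held 7 resting-only and 4 activated-only loops.

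Outside chromosome Y, 1 anchor in each list took part in 6 or more loops. The anchor on chromosome 13 from 22110001 to 22135000, inside the region of long resting-only loops, had 7 loops in resting and 2 in activated cells. The anchor on chromosome 9 from 32370001 to 32425000 had 5 and 6.

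Activated cells had 2.31 times as many called loops, from a map estimated to be 1.55 times as deep at shared loops. Thinned by that single factor, the activated list still held 1.91 times as many loops (1.81 to 2.02). With a factor for each length class it held 1.94 times as many (1.83 to 2.05). With the single factor and a common Poisson limit it held 1.50 times as many (1.41 to 1.60). If the estimate of 1.55 holds, these values argue against depth as the whole cause. Larger assumed depth factors removed the excess: 1903 loops were left at 3.25 and 1753 at 3.5, against 1866 resting loops. These factors were tried with the resting list's own limits alone. Under the common Poisson limit larger factors were not tried, and a smaller one could remove the excess there. The numbers of labelled libraries, 26 activated and 8 resting, differ by more than 1.55 times, but their sizes were not given. How much depth contributed stays open, since the thinned ratio moved with the limit, the loop caller was not rerun on thinned maps and the quality of each map was not measured. A difference that comes with activation may account for the rest and was not tested beyond this, with 1 map per state.

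Resting-only loops had 0.478 of the median length of shared resting loops. With all q-values at most 0.01 in both lists the ratio was 0.478 (0.408 to 0.565, medians 55 and 115 kb). That limit was set on q-values alone, and a strict resting loop with a weaker activated partner then counted as resting-only. In the full lists, 42.0% of resting-only and 30.4% of shared resting loops had a q-value above 0.01. Single-pixel loops made up 23.7% and 10.4%. Weak calls near the threshold therefore stay open. With anchors widened by 25 kb the length ratio was 0.455 (0.409 to 0.50, medians 50 and 110 kb). This argues against a tolerance too narrow for short loops. Short loops might be matched less often between any 2 maps, even of the same state: up to 50 kb, 40.2% of activated loops (36.2 to 44.3) and 41.7% of resting loops were matched, with 323 resting-only and 333 activated-only loops; without repeat lists of a state this cannot be told apart from a change of short loops with activation.

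The 9 resting-only loops over 500 kb on chromosome 13 lay within 2.58 Mb. Too few contacts in the activated map could not be excluded: at the 5 loops of the region in both lists, the expected count was 0.524 to 2.94 times that of the resting map (median 1.43), on both sides of 1 and in part between different pixels. Reads shared between near-identical sequence copies, and a few libraries of the resting pool with unusual contacts, could give the same picture; both stay open, because neither a genome sequence nor single libraries were analysed here. A contact between distant parts of this region that is weaker in activated cells is a hypothesis from the same data. It was not tested, because the activated list gives no counts at these pixels.

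A hypothesis that activated loops reach farther from the same anchor, beyond their greater length in general, was tested. It used 286 pairs of a resting-only and an activated-only loop with a common anchor and direction. The activated loop was the longer one in 69.9% of pairs and in 68.6% of random pairs of the same loops, a difference of 1.36 percentage points (-1.004 to 3.93). After thinning the difference was -0.04. The interval includes 0, so the pairs may reflect no more than the greater length of activated loops in general. Random pairs kept that greater length, so a gain in reach at anchors in general would not show in this difference.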
